A study of Mus musculus with 3 samples.

How the data were processed

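Single-cell libraries were made from cells of the subventricular zone (SVZ), the neurogenic layer on the lateral wall of the lateral ventricle, of adult mice. Per the labels, 5 mice were used, the tissue was dissociated with papain, and cells were sorted by fluorescence before droplet capture with 10x Chromium Single Cell 3' v2 chemistry and sequencing. The mice carried a tamoxifen-dependent Cre under the promoter of smooth muscle actin (Acta2) with a tdTomato reporter, and GFP under control of Sox2. The first library held tdTomato-positive, GFP-positive cells (1200 sorted), and 2 libraries held tdTomato-negative, GFP-positive cells (1200 and 6000 sorted). The labels do not say whether the libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

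The deposited files hold raw UMI counts per gene and barcode, not normalised, as whole numbers in 1 matrix per library. Per the submitters' processing notes, Cell Ranger, STAR and Seurat 1.4.0.15 were used with the builds mm10 and GRCm38.p5. The role and order of these tools, the Cell Ranger version and the rule by which barcodes were called cells are not given in the sources used here. No cell annotation by the authors was used. Each matrix lists 27998 genes and no entry for tdTomato or GFP, so reporter transcripts were not measured.

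Everything from here on was computed from the deposited counts. Barcodes with at least 300 detected genes and at most 25% mitochondrial UMIs were kept. Counts were scaled to 10000 per cell and log-transformed with a pseudocount of 1. Cells of the 3 libraries were clustered together without integration, with 1000 highly variable genes, 20 principal components, 15 neighbours and the Leiden method at resolution 1.0 (scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Python 3.11.15, seed 1). To keep the genes that defined clusters apart from the genes tested between them, clustering used genes whose Ensembl number ends in an even digit plus 140 cell type markers, without the members of the gene lists (13819 genes). Tests between classes used the genes with an odd last digit plus the gene lists, without the markers (14179 genes). This split does not make the tests independent of the clustering. Tested genes can vary together with clustering markers such as Foxj1 and Rsph1 (cilia) or Top2a and Mki67 (cell cycle). Calls of cilium and cell cycle genes between classes therefore describe the classes. Clusters were named from 13 marker lists: the list with the most markers among the cluster's 10 leading genes (detected in at least 25% of its cells, ranked by fold with 20 CPM added) gave the name if no other list had as many and at least 3 of its markers were 2-fold higher in the cluster. The lists for choroid plexus epithelium, fibroblasts and erythroid cells named no cluster. No doublets were removed. Scrublet, tried as an alternative, called 9 cells of the tdTomato-positive library (3.57%), 2 of tdTomato-negative library 1 (0.781%) and 3 of tdTomato-negative library 2 (0.268%).

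Cells are not replicates, so counts were summed per library, or per library and class where a library held at least 10 cells of the class. The sums were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05. The comparison of gates, over all cells and over ependymal-like cells, used 3 sums. It set 1 tdTomato-positive library against 2 tdTomato-negative ones, which leaves 1 residual degree of freedom, and the lone library was assumed to vary like the others. The comparisons of classes used 19 sums with library as a block and 8 residual degrees of freedom. Classes of the same library are paired by construction, which is where the block comes from. Standard errors of log2 fold changes are approximate (the absolute log2 fold change divided by the square root of F). Levels are means over libraries of CPM with their SD.

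Where a group held 0 UMIs of a gene, the fold is given as a lower bound against a floor of 3 counts over the group. Where it held 1 to 3, the ratio of pooled CPM is given with its exact conditional 95% interval. Shares of cells carry exact Clopper-Pearson 95% intervals, and a share of 0 carries the limit that 3 counts would give. These intervals and floors cover counting error only. Shares of cells with a UMI were also computed after thinning each cell to 1000 UMIs, which left out 41, 12 and 6 shallower cells of the tdTomato-positive library and tdTomato-negative libraries 1 and 2.

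The 17 gene lists (534 genes) were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation. No list's call held with the estimated correlation in any comparison. In the gate comparisons that check rests on 1 residual degree of freedom, so it could hardly pass and cannot decide there. Members called were counted after adjustment over all genes tested and after adjustment over the list alone.

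The genes named per comparison are the 12 with the largest absolute log2 fold change in each direction among those passing the threshold, with a mean of at least 50 CPM and the same direction in every library pair (6 not passing where a direction has none). Gene models without a symbol of their own were skipped. Up to 4 called members per gene list (else the 2 most abundant) are named as well, and a fixed set that includes Acta2, Sox2, Foxj1, Gfap, Nes, Prom1, Vim, Cd24a, Mki67, Egfr and Dcx. The text gives a part of these. The tests, the filters, the marker lists, the gene lists, this rule and the alternatives listed next, except where the closing section says otherwise, were chosen before the data were examined.

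The alternatives were RLE scaling, the Wald test of DESeq2 1.42.0, no filter on low counts, a cell filter of 500 genes and 10% mitochondrial UMIs, all deposited barcodes (gate comparison), resolutions 0.5 and 2.0, clustering on the odd-digit genes, Scrublet calls removed, thinned cells, no library block, and each library left out in turn. Leaving out a tdTomato-negative library from a gate comparison leaves 1 library against 1, which gives folds with no test. Gene positions are from GENCODE release M21 on GRCm38. Figures were drawn with matplotlib 3.10.9.

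The steps were tested on simulated data drawn from the real library sizes and the mean of each gene pooled over the sums. A dispersion of 0.05 was set for every gene. Groups differed only in the genes changed on purpose, unlike the real classes and gates, so the shares recovered may not carry over. For the gate comparison, 3.28% of genes changed 2-fold (9933 genes tested) and 51.9% of those changed 4-fold (10021 genes) were recovered. For ependymal-like cells between gates the shares were 0.562% (4045 genes) and 60.7% (4089 genes). Between ependymal-like and astrocyte-like cells they were 11.8% (2472 genes) and 60.6% (2530 genes), and between transit-amplifying-like and astrocyte-like cells 5.50% (2556 genes) and 88.3% (2584 genes).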

Results

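Transcripts of single SVZ cells were counted in 3 libraries. The tdTomato-positive library held 314 barcodes (26.2% of the sorted cells) and 788344 UMIs, a median of 1953.5 per barcode. The tdTomato-negative libraries 1 and 2 held 259 and 1127 barcodes (21.6% and 18.8% of the sorted cells) with 929997 and 3593633 UMIs, medians of 2633 and 2391. After filtering, 252, 256 and 1121 cells were left. The median share of mitochondrial UMIs in kept cells was 8.27% in the tdTomato-positive library and 3.22% and 3.38% in the tdTomato-negative ones. With 1 tdTomato-positive library, that gate has no replicate.

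The first question was which cell types the tdTomato gate, driven by Acta2-promoter Cre, holds among GFP-positive (Sox2) cells. Of 11 clusters, an ependymal-like cluster of 234 cells was led by Ccdc153, Rarres2, Tmem212 and Mia. The astrocyte-like class, which can include quiescent neural stem cells, joined a cluster of 200 cells led by Slc7a10, Htra1 and Ntm with a cluster of 95 cells led by Gfap, Id3 and Thbs4. The transit-amplifying-like class, which can include activated neural stem cells, held 270 cells led by Top2a, Hmgb2 and Cenpf. Neuroblast-like cells numbered 479 (led by Stmn2, Shtn1 and Meg3). A neuron-like cluster of 204 cells led by Prokr2, Meg3, Pbx3 and Foxp2 had 1 marker, Meg3, among its 10 leading genes. In the tdTomato-negative libraries 1 and 2 its neuroblast markers summed to 12394 and 10111 CPM and its neuron markers to 5168 and 6470, against neuroblast markers of 12484 and 12829 in neuroblast-like cells. Smaller classes were oligodendrocyte-like (56 cells), oligodendrocyte precursor-like (49), endothelial-like (20), microglia-like (14) and mural-like (8).

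Ependymal-like cells made up 70.2% of the tdTomato-positive library (177 of 252 cells; 95% interval 64.2% to 75.8%), against 4.69% (2.45% to 8.04%) and 4.01% (2.94% to 5.33%) of the tdTomato-negative libraries 1 and 2. Transit-amplifying-like cells made up 18.75% (14.2% to 24.1%) and 19.7% (17.4% to 22.2%) of the tdTomato-negative libraries, and 1 cell of the tdTomato-positive one (0.397%; 0.01% to 2.19%). With odd-digit clustering the shares in the tdTomato-negative libraries were 11.3% and 11.2%. The 1 tdTomato-positive cell held 557 UMIs, 330 genes and 23.5% mitochondrial UMIs, close to the filter limits. The class had medians of 6014 UMIs and 3.23%. Neuroblast-like cells made up 31.25% and 35.5% of the tdTomato-negative libraries and 0.397% of the tdTomato-positive one (17.8% and 24.98% of the tdTomato-negative libraries under the stricter cell filter, 23.05% and 21.9% at resolution 2.0). Astrocyte-like cells made up 17.6% (13.1% to 22.8%) and 20.9% (18.5% to 23.4%) of the tdTomato-negative libraries and 6.35% (3.67% to 10.1%) of the tdTomato-positive one (4.43% under the stricter cell filter, 9.92% with odd-digit clustering). The neuron-like shares were 19.1% and 13.7% of the tdTomato-negative libraries, with 0.397% in the tdTomato-positive one (24.8% and 24.4% with Scrublet calls removed). Oligodendrocyte-like cells made up 5.56%, 3.91% and 2.85% of the tdTomato-positive library and the tdTomato-negative libraries 1 and 2 (5.56%, 1.17% and 1.78% at resolutions 0.5 and 2.0). Endothelial-like (7.94%), microglia-like (5.56%) and mural-like cells (3.17%) all came from the tdTomato-positive library, so each of these clusters may be that library. A mural-like cluster was found again at resolution 2.0 but not at resolution 0.5, under the stricter cell filter, with odd-digit clustering or with Scrublet calls removed. Under the stricter cell filter 23 tdTomato-positive cells were endothelial-like, with the mural markers Vtn and Rgs5 among the cluster's leading genes. In the tdTomato-negative libraries, 0 endothelial-like, microglia-like or mural-like cells allow shares of up to 1.17% and 0.268% for each class. The 2 sort gates can set all these shares. With 1 library on the tdTomato-positive side, no test between gates was made for shares.

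**Figure D1:**
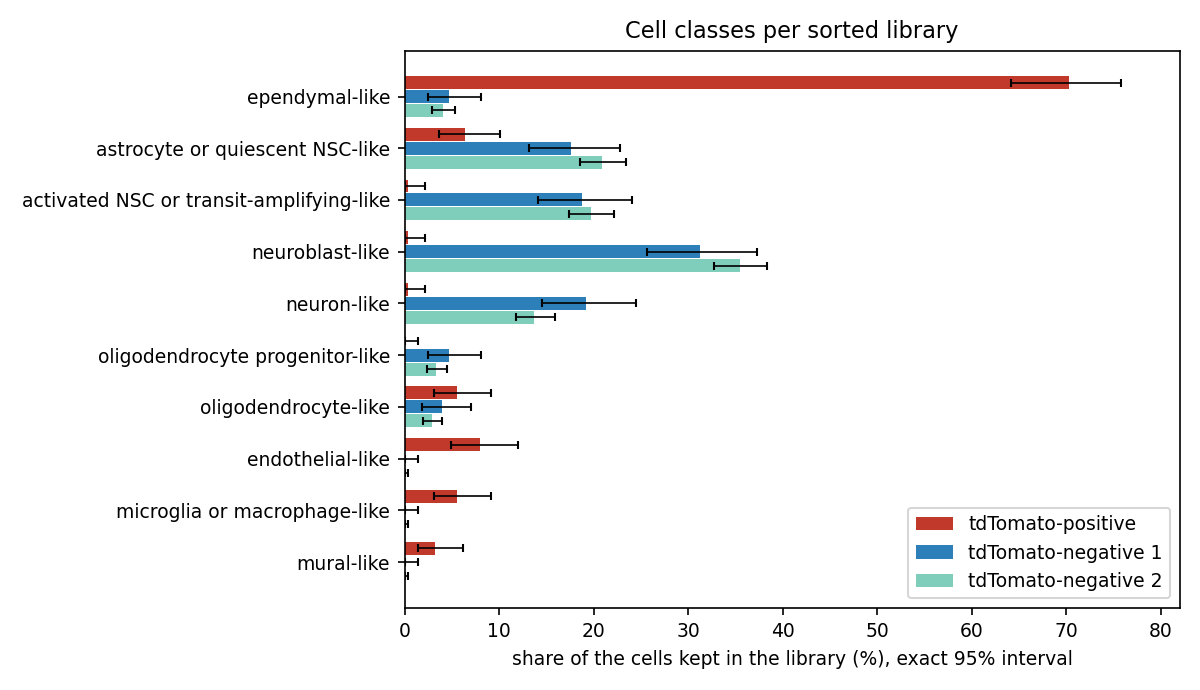
Share of kept cells (percent) in each class per library, with exact 95% intervals as error bars. Ependymal-like cells took 70.2% of the tdTomato-positive library and 4.69% and 4.01% of the tdTomato-negative ones.

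Acta2 (chromosome 19, 34241090 to 34255590, minus strand, GRCm38) was detected in 70.1% of ependymal-like cells of the tdTomato-positive library (124 of 177; 62.7% to 76.7%; 605 CPM, UMIs scaled to those of the summed cells). In ependymal-like cells of the tdTomato-negative libraries it was detected in 41.7% (5 of 12; 15.2% to 72.3%; 356 CPM) and 44.4% (20 of 45; 29.6% to 60%; 253 CPM). After thinning to 1000 UMIs the 3 shares were 45.6%, 27.3% and 13.3%. In transit-amplifying-like cells, which should lack Acta2, 2.22% of cells had a UMI, at a median depth of 6014 UMIs against 3632.5 in ependymal-like cells. The tdTomato label depends on Cre driven by the Acta2 promoter and on tamoxifen, so it need not mirror Acta2 transcripts at sorting. The tdTomato gate can set these shares. Foxj1 (chromosome 11, 116330704 to 116335399, minus strand), a regulator of motile ciliogenesis, was detected in 71.8%, 75.0% and 73.3% of ependymal-like cells of the tdTomato-positive library and the tdTomato-negative libraries 1 and 2. Over all libraries it was detected in 72.2% of them (thinned 39.8%), in 3.57% of oligodendrocyte-like cells (median 4185.5 UMIs) and in 2.71% of astrocyte-like cells (median 2401 UMIs; thinned 1.41%).

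Sox2 (chromosome 3, 34650405 to 34652461, plus strand), read by the GFP gate, was detected in 49.1% of ependymal-like cells (thinned 20.4%; 228 CPM), 38.0% of astrocyte-like cells (thinned 18.0%; 236 CPM) and 64.8% of transit-amplifying-like cells (thinned 19.3%; 207 CPM). It was found in 1 of 20 endothelial-like cells (median 1072 UMIs) and 0 of 14 microglia-like cells (median 1681 UMIs). Gfap (chromosome 11, 102887336 to 102900912, minus strand), an intermediate filament gene of astrocytes and neural stem cells, was detected in 24.4% of astrocyte-like cells (thinned 16.5%; 401 CPM) and 12.4% of ependymal-like cells (thinned 2.78%; 38.4 CPM), against 8.93% of oligodendrocyte-like cells (thinned 0). The proliferation gene Mki67 (chromosome 7, 135689784 to 135716361, minus strand) was detected in 54.4% of transit-amplifying-like cells (48.3% to 60.5%; thinned 15.6%) and 1.71% of ependymal-like cells (4 of 234; 0.468% to 4.32%; thinned 0.463%). Oligodendrocyte-like cells, with oligodendrocyte precursor markers at 1781 CPM in the tdTomato-positive library and 4551 and 2664 in the tdTomato-negative ones, had it in 12.5% (5.18% to 24.1%; thinned 6.12%). Egfr (chromosome 11, 16752203 to 16918158, plus strand), a gene of activated progenitors, was detected in 2.14% of ependymal-like cells, 25.9% of transit-amplifying-like cells and 3.57% of oligodendrocyte-like cells. Over all libraries Egfr was at 72.2 CPM in transit-amplifying-like cells, 59.9 and 58.2 in the astrocyte-like clusters and 6.20 in ependymal-like cells. Its level therefore hardly separated transit-amplifying-like from astrocyte-like cells. Dcx (chromosome X, 143855842 to 143933311, minus strand), a neuroblast gene, was detected in 1.71% of ependymal-like, 67.4% of transit-amplifying-like and 16.1% of oligodendrocyte-like cells. After thinning, Egfr and Dcx were detected in 1.39% and 0.463% of ependymal-like and 5.58% and 24.9% of transit-amplifying-like cells. Endothelial-like (median 1072 UMIs) and microglia-like cells (median 1681 UMIs) had Mki67, Egfr and Dcx in 0 of 20 and 0 of 14 cells, too shallow to limit these shares. Whether the few UMIs of these 3 genes in ependymal-like cells are background was not tested. Acta2, Foxj1, Mki67, Egfr and Dcx were among the clustering markers, so their levels describe the classes, while Sox2 and Gfap were kept out of the clustering.

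**Figure D2:**
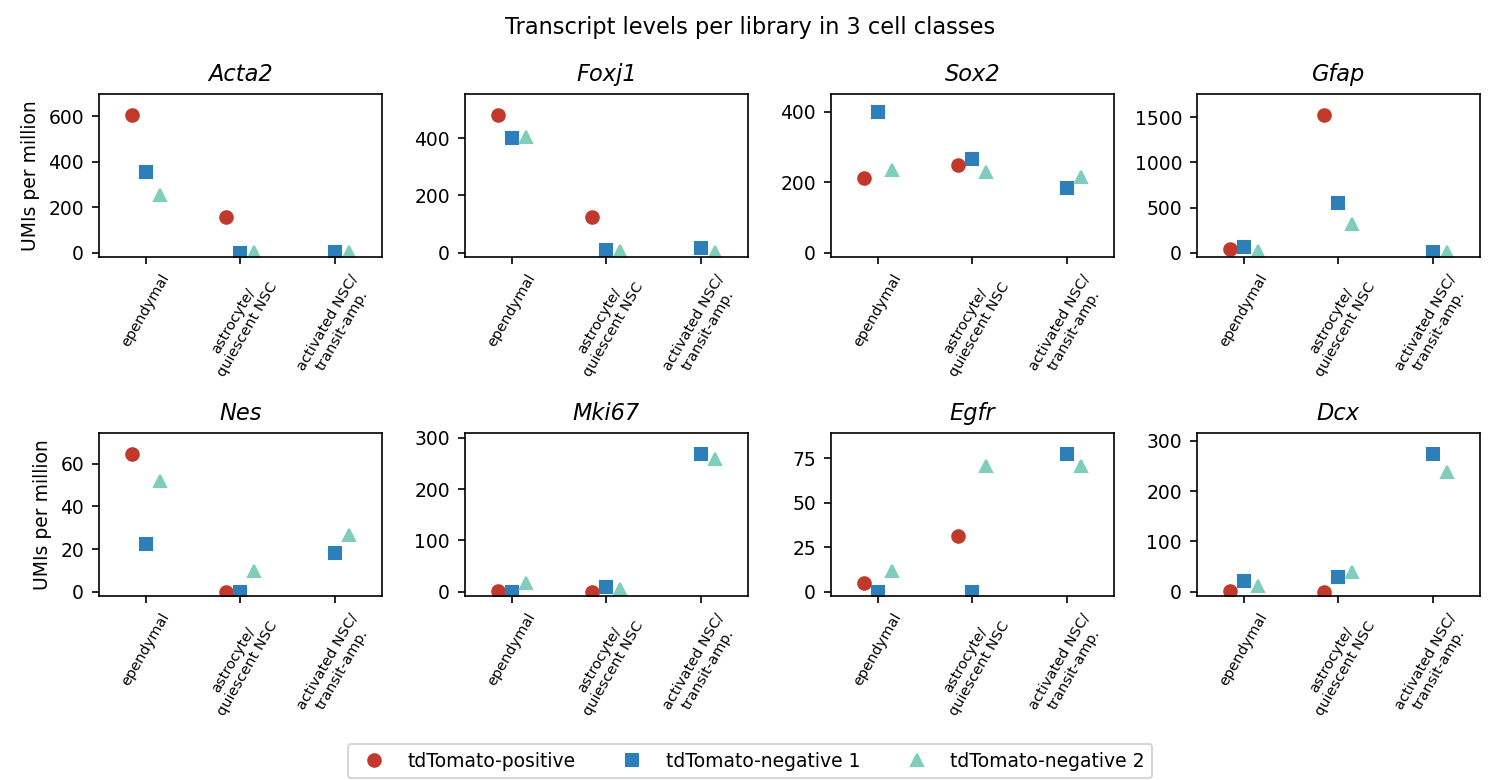
CPM of 8 marker genes in ependymal-like, astrocyte-like and transit-amplifying-like cells, per library with at least 10 cells of the class. Acta2 in ependymal-like cells was 605 in the tdTomato-positive library and 356 and 253 in the tdTomato-negative ones.

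The comparison of the gates over all kept cells asked which transcripts separate the tdTomato-positive from the tdTomato-negative cells (1 library against 2). Values with ± are log2 fold changes with their approximate standard error, or mean CPM with their SD over libraries. Acta2 rose by 4.90 ± 0.33 (508 against 18.5 ± 4.42 CPM; adjusted p = 2.96e-46) and Foxj1 by 3.89 ± 0.31 (404 against 29.7 ± 8.43). Motile cilium genes rose with 55 of 56 axoneme members called higher and 1 lower, the same adjusted over the list alone. Among them, Lrrc23 rose by 4.32 ± 0.33, Dnah6 (a dynein heavy chain) by 4.21 ± 0.34 and Zmynd10 (dynein arm assembly) by 4.24 ± 0.36. Of 9 regulators of multiciliation, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with Trp73 at 4.38 ± 0.63 and Ccdc78 at 3.06 ± 0.35. Ucma rose by 5.03 ± 0.34 (336 against 10.8 ± 1.5 CPM). Genes of the clusters found in the tdTomato-positive library alone were higher as well. The complement gene C1qa (292 CPM) and the endothelial tight junction gene Cldn5 (285 CPM) had 0 UMIs in the tdTomato-negative libraries, so their log2 fold changes were at least 8.78 and 8.74.

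Cell cycle members fell, 38 of 40 lower and 0 higher (the same adjusted over the list alone). Top2a, a clustering marker outside the list, and the list member Ube2c had 0 UMIs in the tdTomato-positive library, log2 fold changes of -6.57 and -6.27 at the floor, so they were at least that far lower. Mki67 had a ratio of -5.39 on the log2 scale (counting interval -8.44 to -3.53), and Dcx -6.31 (-8.59 to -4.76). Of 29 neuronal differentiation genes, 26 fell and 1 rose (27 and 1 adjusted over the list alone), among them Sox11 at -6.66 ± 0.51 (16.7 against 1774 ± 338 CPM). Igfbpl1 (734 ± 40.8 CPM in the tdTomato-negative libraries, 0 UMIs in the other) reached the floor at -7.49. Egfr fell by 2.78 ± 0.61 in the edgeR test, with adjusted p = 0.0587 in DESeq2. The cell cycle list (camera adjusted p = 7.75e-27) had adjusted p = 0.570 with an estimated correlation, and the cilium list (2.47e-51) had adjusted p = 0.584 with an estimated correlation.

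Of 20 interferon and antigen presentation genes 16 rose and 0 fell, with Ifitm3 at 3.82 ± 0.32 and Psmb9 at 4.43 ± 0.94. Immediate early and dissociation stress genes rose for 19 of 34 and fell for 2 (20 and 2 adjusted over the list alone), with Atf3 at 5.10 ± 0.68 and Cyr61 at 3.51 ± 0.37, beside the higher mitochondrial share of that library. Metallothionein and redox genes rose for 16 of 24 and fell for 2 (18 and 3 adjusted over the list alone), with Mt3 at 2.74 ± 0.31 and Gsta4 at 2.81 ± 0.31. Smooth muscle contraction genes rose for 8 of 13 and fell for 0 (10 and 0 adjusted over the list alone), with Myl9 at 4.10 ± 0.36 and Synpo2 at 3.95 ± 0.53. Adhesion and junction genes rose for 12 of 25 and fell for 2 (13 and 2 adjusted over the list alone), such as Cdhr4 (4.09 ± 0.32) and Celsr1 (3.25 ± 0.46). Ion and water transport genes rose for 10 of 17 and fell for 1. Ribosomal protein genes fell for 12 of 57 and rose for 0 (18 and 1 under RLE scaling), with Rpl35 at -1.35 ± 0.34.

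Stem and progenitor markers went both ways, 7 of 26 higher and 6 lower (8 and 6 adjusted over the list alone). Nes rose by 2.04 ± 0.38, Sox9 by 1.89 ± 0.30, Vim by 1.48 ± 0.30 and Prom1 by 1.79 ± 0.50 (adjusted p = 0.213 in DESeq2). The Notch list had 5 of 14 members higher and 2 lower (5 and 3 adjusted over the list alone). Its member Hes5, a Notch target, fell by 4.51 ± 0.55, with -5.14 without tdTomato-negative library 1 and -3.41 without library 2. The BMP list had 2 of 13 higher and 1 lower (1 and 1 adjusted over the list alone). Lipid metabolism had 12 of 37 higher and 6 lower, with Dbi at 2.80 ± 0.32. Glycolysis had 4 of 16 higher and 1 lower, with the glucose transporter Slc2a1 at 3.65 ± 0.31. The respiratory chain had 1 of 40 higher and 1 lower (0 and 0 adjusted over the list alone). Sox2 (0.02 ± 0.32; 189 against 193 ± 4.26 CPM; adjusted p = 0.971), Gfap (0.72 ± 0.32; adjusted p = 0.0584; 0.0312 under RLE scaling) and Cd24a (0.32 ± 0.31; adjusted p = 0.431) did not pass. In all, 4579 of 10944 genes passed (2501 higher, 2078 lower), and 1908 in DESeq2. Every gene called in these gate paragraphs had the same direction against each tdTomato-negative library. The libraries differed in cell makeup (70.2% against 4.69% and 4.01% ependymal-like cells), which is part of these folds. The 20 endothelial-like cells, all tdTomato-positive, held Nes at 233 CPM and Prom1 at 204 CPM. Ependymal-like cells of all libraries held these 2 genes at 59.5 and 24.8 CPM. The endothelial-like cells are therefore part of the Nes and Prom1 folds as well. Camera with the preset correlation passed 11 of 17 lists and with an estimated correlation 0 (lowest adjusted p = 0.570). The latter rests on 1 residual degree of freedom, could hardly pass and cannot decide whether these list calls hold.

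Ependymal-like cells were then compared between gates (177 cells against 12 and 45), which asks whether tdTomato-positive ependymal cells differ from the tdTomato-negative ones. Of 4098 genes, 7 were higher and 5 lower, and 0 passed in DESeq2 (9 at an unadjusted p under 0.05, against 133 in edgeR). The tubulin-binding gene Stmn1 fell, at -2.22 ± 0.34 (124 against 619 ± 5.16 CPM; adjusted p = 1.19e-07) as did the tubulin gene Tubb2b, at -3.22 ± 0.62 (13.6 against 156 and 132). Tubb5 fell by 1.93 ± 0.42 (59.5 against 230 ± 41.5; -1.34 without tdTomato-negative library 2). The histone gene Hist2h2aa1 fell by 1.25 ± 0.32 (-0.48 without tdTomato-negative library 2, adjusted p = 0.123 under the stricter cell filter). Ucma rose by 1.4 ± 0.35 (410 against 222 and 144), Camk2n1 by 2.52 ± 0.60 (153 against 44.5 and 23) and the immediate early gene Fos by 1.55 ± 0.38 (313 against 178 and 92.0; adjusted p = 0.306 under the stricter cell filter, 0.175 with odd-digit clustering and 0.389 without the count filter). Without the count filter, Tubb5 (adjusted p = 0.142), Hist2h2aa1 (0.978) and Ucma (0.415) did not pass either. The myelin gene Mbp had a log2 ratio of 5.25 (counting interval 3.38 to 8.31; 348 against 0 and 11.5 CPM). Ttr, a choroid plexus gene, was at least 3.62 higher on the log2 scale (99 UMIs against 0). Kif5a (90.1 against 44.5 and 0 CPM), Gm42418 (1.35 ± 0.33) and Hist1h2ap (5.10 against 0 and 184 CPM) complete the 12. These 3 lie outside the naming rule and were chosen after their values were seen. For Hist1h2ap the tdTomato-negative libraries lay on both sides of the tdTomato-positive one. The other 11 kept 1 direction against both libraries.

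In the same cells, 0 of 54 cilium axoneme genes and 0 of 5 multiciliation regulators passed, with Foxj1 at 0.35 ± 0.31 (481 against 402 ± 1.62). Acta2 was at 1.19 ± 0.32 (605 against 305 ± 72.7; adjusted p = 0.0692) and did not pass. Sox2 (-0.32 ± 0.34), Vim (0.43 ± 0.30), Nes (0.59 ± 0.63), Cd24a (0.60 ± 0.30) and Gfap (0.58 ± 1.32) did not pass either. Of the lists, neuronal differentiation had 2 of 14 members lower, Stmn1 and Tubb2b (4 lower and 1 higher adjusted over the list alone), with a camera adjusted p = 4.08e-07 and adjusted p = 0.875 with an estimated correlation. The stress list had 1 of 22 higher, Fos. The others had 0 members called in edgeR, including 6 cell cycle, 19 stem and progenitor, 3 Notch, 4 BMP, 24 lipid metabolism, 11 glycolysis, 40 respiratory chain and 57 ribosomal protein genes. Camera passed 4 of 17 lists and 0 with an estimated correlation, a check that cannot decide with 1 residual degree of freedom. Besides neuronal differentiation these were ion and water transport (adjusted p = 0.0429), adhesion (0.0429) and ribosomal proteins (0.0476, and 0.110 under RLE scaling), all 3 upward. Marker sums of other cell types differed between these cells. Oligodendrocyte markers summed to 716 CPM in tdTomato-positive ependymal-like cells against 222 and 316, choroid plexus markers to 491 against 178 and 265, and neuroblast markers to 105 against 556 and 414. Stmn1 in oligodendrocyte-like cells was at 2782 CPM in the tdTomato-positive library and 1004 and 2376 in the tdTomato-negative ones. The median mitochondrial share was 9.11% against 6.32% and 7.29%. On simulated data, 0.562% of genes changed 2-fold and 60.7% of genes changed 4-fold were recovered in this comparison. Most 2-fold differences were thus missed in the simulation and may be missed in the real cells as well.

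**Figure D3:**
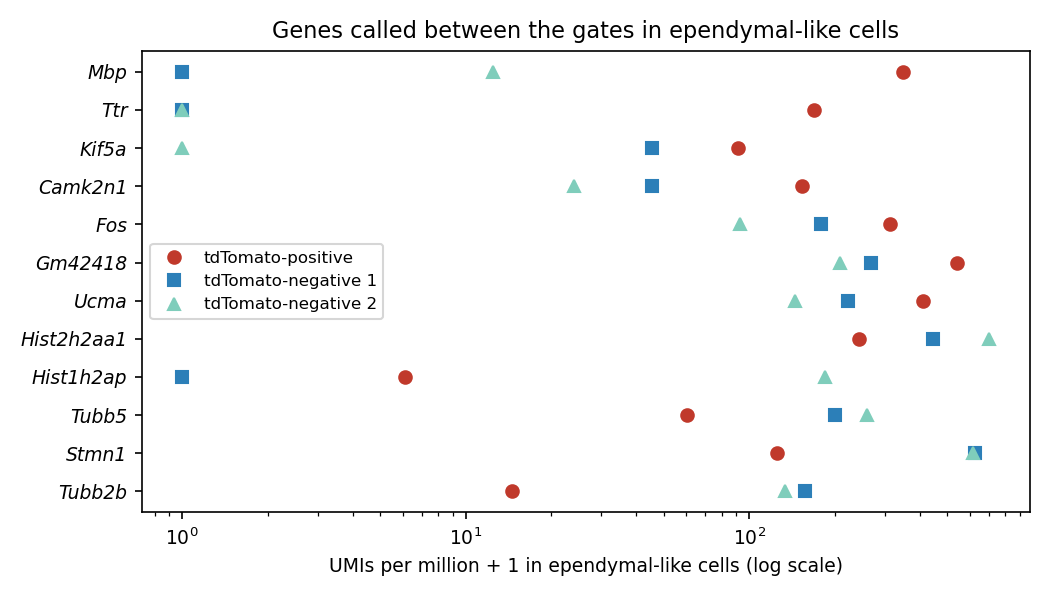
CPM plus 1 (log axis) in ependymal-like cells of each library for the 12 genes that passed between gates. Stmn1 was at 124 in the tdTomato-positive library and 619 ± 5.16 in the tdTomato-negative ones, while Hist1h2ap was at 0 in tdTomato-negative library 1.

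Ependymal-like and astrocyte-like cells (3 libraries each, paired by library) were compared to ask how ependymal cells differ from the class that can include quiescent neural stem cells. All 51 tested cilium axoneme genes rose, 51 adjusted over the list alone (23 of the 23 tested without tdTomato-negative library 2). Clustering markers such as Foxj1 and Rsph1 helped define the ependymal-like class, so this count describes the class. The inner arm dynein Dnah12 had a log2 ratio of 8.50 (counting interval 6.01 to 13.81; 504 ± 24.7 CPM in ependymal-like cells). Outside the list, Fam216b (234 ± 22.9 CPM) had 0 UMIs in astrocyte-like cells and was at least 5.94 higher on the log2 scale. Of 6 multiciliation regulators 4 rose, among them Myb, at least 4.31 higher, and Rfx2 with a ratio of 4.37 (2.43 to 7.46; adjusted p = 0.239 in DESeq2). The surface marker Cd24a rose by 3.56 ± 0.34 (822 ± 169 against 61.3 ± 8.24). Smooth muscle contraction genes rose for 7 of 9 (2 of 6 without tdTomato-negative library 2), with the caldesmon gene Cald1 at 4.98 ± 0.42. Mural markers, which include Acta2, were higher as a sum. In the tdTomato-positive library and the tdTomato-negative libraries 1 and 2 they summed to 746, 467 and 311 CPM in ependymal-like cells. The sums in astrocyte-like cells were 218, 178 and 140. Among the genes that fell, the glutamate receptor gene Gria2 was at -6.90 ± 0.49, Mfge8 at -5.34 ± 0.33 (48.6 ± 20 against 1829 ± 320), Dclk1 at -5.02 ± 0.32 and Cspg5 at -4.91 ± 0.35.

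Stem and progenitor markers fell for 12 of 24 and rose for 4, the same adjusted over the list alone (8 and 3 without tdTomato-negative library 1, 5 and 1 without library 2). Gfap fell by 4.38 ± 0.35 (42.2 ± 24.7 against 798 ± 640; adjusted p = 2.26e-33) and was at -3.78 without the tdTomato-positive library. When the Gfap, Id3 and Thbs4 cluster was left out of the astrocyte-like class, Gfap was at -1.15 (adjusted p = 0.127). Vim rose by 1.77 ± 0.28 (1.45 with adjusted p = 0.106 without tdTomato-negative library 2). Nes rose by 2.51 ± 0.80 (adjusted p = 0.00732; 5.56 with adjusted p = 0.192 without tdTomato-negative library 2). Against the Gfap, Id3 and Thbs4 cluster alone, Vim was at 0.61 (adjusted p = 0.156) and Nes at 1.14 (adjusted p = 0.463). Sox2 (0.15 ± 0.29; 283 ± 102 against 249 ± 18; adjusted p = 0.769) and Prom1 (1.46 ± 1.08; adjusted p = 0.337) did not pass. Of 11 Notch genes 5 fell and 0 rose (4 without tdTomato-negative library 1, 3 without library 2), with Lfng at -2.98 ± 0.35. The Notch target Hes1 was at -1.75 ± 0.26, and at 0.42 (adjusted p = 0.575) against the Gfap, Id3 and Thbs4 cluster alone. Of 11 BMP genes 5 fell and 1 rose (6 and 1 adjusted over the list alone; 3 and 0 without tdTomato-negative library 2), with the BMP target Id2 at -2.79 ± 0.28 (154 ± 32.3 against 1073 ± 151).

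Lipid metabolism genes fell for 16 of 32 and rose for 3 (18 and 3 adjusted over the list alone; 8 and 2 without tdTomato-negative library 1, 3 and 2 of 12 tested without library 2), such as the sterol genes Insig1 (-3.17 ± 0.54) and Idi1 (-3.11 ± 0.59). Ion and water transport genes fell for 9 of 17 and rose for 2 (5 and 1 without tdTomato-negative library 2). Glycolysis genes fell for 8 of 15 and rose for 1 (10 and 1 adjusted over the list alone), but 0 were called without tdTomato-negative library 1, and 1 fell and 1 rose without library 2. Ribosomal protein genes rose for 33 of 57 (40 adjusted over the list alone), for 2 without tdTomato-negative library 1 and for 7 without library 2. Against the Gfap, Id3 and Thbs4 cluster alone, ribosomal protein genes rose for 1 and fell for 2 (median log2 fold change -0.19), ion and water transport genes fell for 5 and rose for 1, and glycolysis genes fell for 4 and rose for 1. Stress genes rose for 15 of 31 and fell for 2 (17 and 2 adjusted over the list alone; 9 and 1 without tdTomato-negative library 1, 7 and 1 without library 2), with Hsp90aa1 at 3.81 ± 0.28. Median mitochondrial shares were 9.11%, 6.32% and 7.29% in ependymal-like cells of the tdTomato-positive library and the tdTomato-negative libraries 1 and 2, against 8.88%, 4.79% and 4.78% in astrocyte-like cells. Redox genes rose for 8 of 23 and fell for 2 (4 and 1 without tdTomato-negative library 1, 1 and 1 without library 2). Interferon genes rose for 4 of 14 (1 without tdTomato-negative library 1, 1 without library 2, 2 without the tdTomato-positive library). Ifitm3 rose by 4.55 ± 0.34. Adhesion genes rose for 5 of 18 and fell for 5 (4 and 2 without tdTomato-negative library 1, 1 and 0 without library 2; 5 and 2 without the tdTomato-positive library).

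Cell cycle genes did not separate the 2 classes as a list (camera adjusted p = 0.9754), with 2 of 36 called higher and 0 lower (1 higher without tdTomato-negative library 1, 0 without library 2, and 1 higher and 2 lower without the tdTomato-positive library). In total 1046 of 3386 genes passed (637 higher, 409 lower), with 627 of 4227 without tdTomato-negative library 1 and 211 of 1306 without library 2. Every gene named as called kept its direction in all 3 library pairs. Camera passed 11 of 17 lists and 0 with an estimated correlation. Cilium axoneme (3.19e-27) had adjusted p = 0.140 with an estimated correlation, and lipid metabolism (0.000275) had adjusted p = 0.205 with an estimated correlation.

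**Figure D4:**
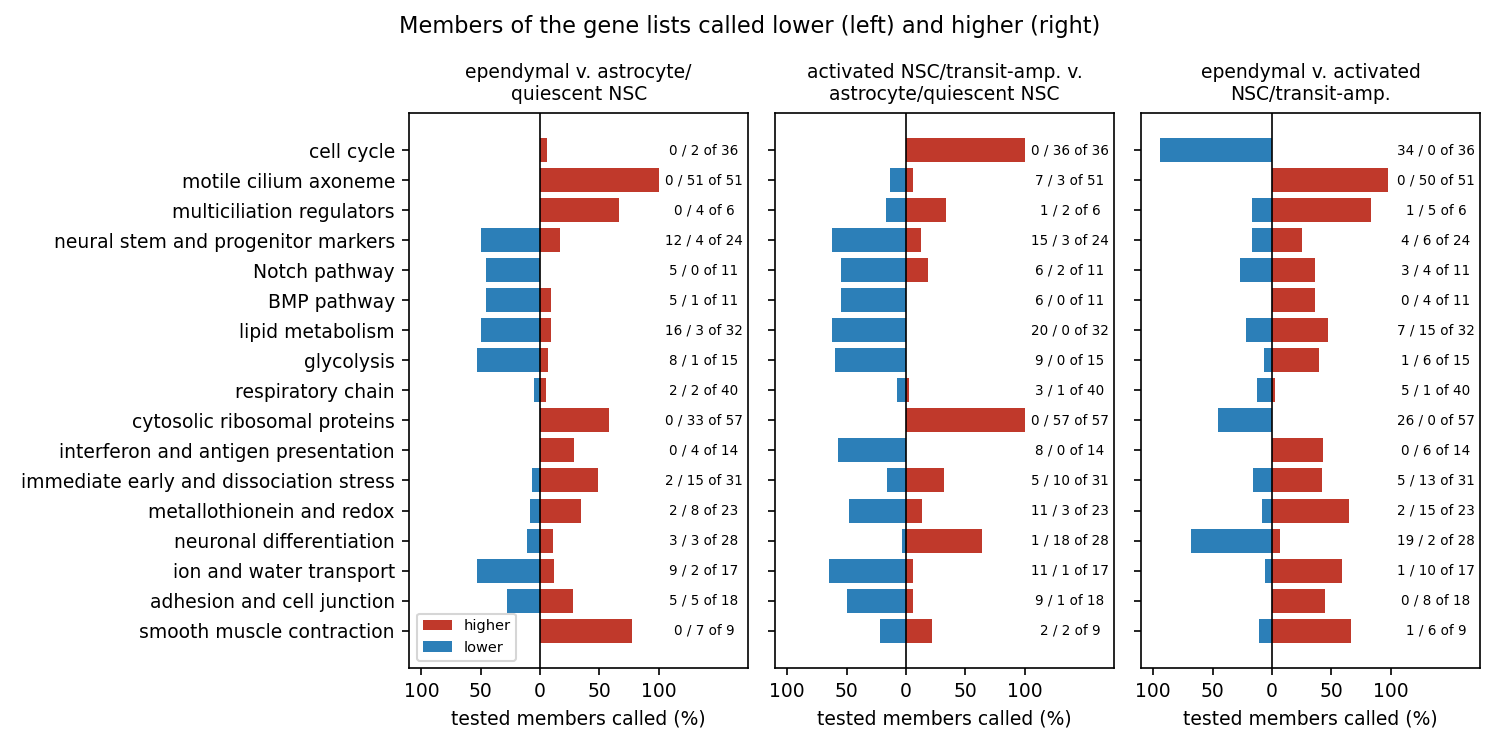
Percent of tested members of each gene list called lower (left) or higher (right) in the 3 class comparisons, with the counts printed. Cilium axoneme genes were higher for 51 of 51 in ependymal-like against astrocyte-like cells, and cell cycle genes for 36 of 36 in transit-amplifying-like against astrocyte-like cells; under RLE scaling 2 ribosomal protein genes were called higher and 27 lower in ependymal-like against transit-amplifying-like cells.

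Transit-amplifying-like and astrocyte-like cells were compared to ask how a class of dividing progenitors differs from the astrocyte-like one (2 libraries against 3). All 36 cell cycle genes tested rose, 36 adjusted over the list alone (15 of 19 tested without tdTomato-negative library 2). The clustering markers Top2a and Mki67 helped define the transit-amplifying-like class, so this count describes the class. Nusap1, a spindle gene, rose by 5.81 ± 0.45 (472 ± 48 against 5.48 ± 5.02) and the replication helicase gene Mcm3 had a ratio of 6.64 (counting interval 4.15 to 11.95). Neuronal differentiation genes rose for 18 of 28 and fell for 1 (22 and 1 adjusted over the list alone; 9 and 0 without tdTomato-negative library 2), with Sox11 at 3.65 ± 0.33 and Stmn1 at 3.59 ± 0.29. Neuroblast markers summed to 6053 and 5656 CPM in transit-amplifying-like cells of the tdTomato-negative libraries, beside 8022 and 7321 for the markers of that class, and to 513 and 563 in astrocyte-like cells. Ribosomal protein genes rose for 57 of 57, but for 3 without tdTomato-negative library 1, 16 without library 2 and 41 against the Gfap, Id3 and Thbs4 cluster alone, with Rplp0 at 2.02 ± 0.27. Cd24a rose by 3.60 ± 0.34 and the Notch ligand Dll3 by 3.45 ± 0.64. Stem and progenitor markers fell for 15 of 24 and rose for 3 (15 and 4 adjusted over the list alone; 8 and 1 without tdTomato-negative library 1, 8 and 1 without library 2). Among them, Gfap was at -5.29 ± 0.35, Fgfr3 at -5.06 ± 0.36 and Vcam1 at -5.05 ± 0.55. Of 11 Notch genes 6 fell and 2 rose (3 and 0 without tdTomato-negative library 2), with Hey1 at -3.83 ± 0.62. Of 11 BMP genes 6 fell and 0 rose (3 without tdTomato-negative library 2), with the receptor gene Bmpr1b at -3.10 ± 0.74 (adjusted p = 0.648 in DESeq2).

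Lipid metabolism had 20 of 32 members lower and 0 higher (21 adjusted over the list alone; 10 without tdTomato-negative library 1, 6 of 12 without library 2), with Apoe at -4.66 ± 0.31 (658 ± 97.9 against 16208 ± 4900) and Acsbg1 at -4.93 ± 0.36. Glycolysis had 9 of 15 lower (10 adjusted over the list alone; 5 without tdTomato-negative library 1, 4 without library 2), with Aldoa at -3.47 ± 0.30. Ion and water transport had 11 of 17 lower and 1 higher (7 lower without tdTomato-negative library 2), with the bicarbonate transporter Slc4a4 at -5.85 ± 0.41. Redox genes had 11 of 23 lower and 3 higher (7 and 1 without tdTomato-negative library 1, 7 and 0 without library 2), with Mt3 at -4.12 ± 0.31 and Gstm1 at -4.16 ± 0.31, while the median mitochondrial shares were 2.87% and 3.29% against 4.79% and 4.78% in the tdTomato-negative libraries. Interferon genes had 8 of 14 lower (1 without tdTomato-negative library 1, 0 without library 2), with H2-K1 at -3.58 ± 0.63 (adjusted p = 0.100 without tdTomato-negative library 2). Of other genes that fell, Pla2g7 was at -6.33 ± 0.36 and Sdc4 at -6.04 ± 0.41. Adhesion genes had 9 of 18 lower and 1 higher (4 without tdTomato-negative library 1, 0 without library 2). Stress genes had 10 of 31 higher and 5 lower (4 and 2 without tdTomato-negative library 1, 4 and 1 without library 2), and cilium genes 3 of 51 higher and 7 lower (2 and 1 without tdTomato-negative library 1, 0 and 0 without library 2). Vim rose by 1.18 ± 0.28 (adjusted p = 0.126 without tdTomato-negative library 1 and 0.428 without library 2; 0.609 against the Gfap, Id3 and Thbs4 cluster alone). Sox2 (-0.37 ± 0.26; adjusted p = 0.254; 0.0114 under RLE scaling), Nes (1.55 ± 0.73; adjusted p = 0.0694; 0.00038 under the stricter cell filter) and Prom1 (1.09 ± 0.90; adjusted p = 0.342) did not pass. In total 1539 of 3386 genes passed (754 higher, 785 lower; 49.0% higher), with 666 without tdTomato-negative library 1 and 237 without library 2. RLE scaling moved the median of all genes by -0.18 on the log2 scale. Every gene named as called had the same direction in both library pairs. Camera passed 11 of 17 lists and 0 with an estimated correlation; cell cycle (6.30e-15) and ribosomal proteins (1.48e-19) each had adjusted p = 0.230 with an estimated correlation.

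Ependymal-like and transit-amplifying-like cells were compared to ask whether ependymal cells carry transcripts of dividing progenitors (3 libraries against 2). Cilium and cell cycle markers helped define these classes, so the calls of these 2 lists describe the classes. Cell cycle genes fell for 34 of 36 and rose for 0, 34 adjusted over the list alone (12 of 19 tested without tdTomato-negative library 2). Cyclin B1 (Ccnb1) had 0 UMIs against 573 and reached the floor at -6.44, as did Ccnb2 at -5.50 and, outside the list, the chromatin helicase gene Hells at -5.17. Nusap1 had a ratio of -7.52 (counting interval -10.56 to -5.66) and the survivin gene Birc5 -8.13 (-13.44 to -5.65). Cilium axoneme genes rose for 50 of 51 (50 higher and 1 lower adjusted over the list alone; 22 of 23 without tdTomato-negative library 2), with Cfap52 (152 ± 23 CPM) at least 6.36 higher. Neuronal differentiation genes fell for 19 of 28 and rose for 2 (21 and 2 adjusted over the list alone; 12 and 1 without tdTomato-negative library 1, 7 and 0 without library 2), with Elavl3 at -4.57 ± 0.50. Redox genes rose for 15 of 23 and fell for 2 (9 and 0 without tdTomato-negative library 1, 7 and 0 without library 2), with Gsta4 at 5.77 ± 0.49 and Mt3 at 5.08 ± 0.33. Median mitochondrial shares were 6.32% and 7.29% in ependymal-like and 2.87% and 3.29% in transit-amplifying-like cells of the tdTomato-negative libraries. Lipid metabolism genes rose for 15 of 32 and fell for 7 (9 and 2 without tdTomato-negative library 1, 4 and 0 without library 2), with Dbi at 4.06 ± 0.31 and Apoe at 3.55 ± 0.30. Ion and water transport genes rose for 10 of 17 and fell for 1 (3 and 1 without tdTomato-negative library 2). Fxyd1, outside the list, was at 4.63 ± 0.33. Smooth muscle genes rose for 6 of 9 and fell for 1 (3 and 0 without tdTomato-negative library 2), with Myl9 at a ratio of 6.41 (4.82 to 8.71). Mural markers, which include Acta2, summed to 467 and 311 CPM in ependymal-like cells of the tdTomato-negative libraries 1 and 2. In transit-amplifying-like cells of these libraries they summed to 5.17 and 7.95. Interferon genes rose for 6 of 14 (2 of 6 without tdTomato-negative library 2), with Ifitm3 at 6.57 ± 0.38.

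Ribosomal protein genes fell for 26 of 57 and rose for 0 (27 and 2 under RLE scaling), but 0 were called without tdTomato-negative library 1 or without library 2, and 44 fell and 2 rose without the tdTomato-positive library. Stem and progenitor markers rose for 6 of 24 and fell for 4 (4 and 0 without tdTomato-negative library 2; 6 and 0 without library 1). Vim (0.59 ± 0.27; adjusted p = 0.0645; 0.000847 without the tdTomato-positive library and 2.56e-05 under RLE scaling), Sox2 (0.52 ± 0.30; adjusted p = 0.149; 0.0184 under RLE scaling), Nes (0.95 ± 0.67; adjusted p = 0.256; 0.0231 without the library block), Prom1 (0.38 ± 0.95; adjusted p = 0.782), Cd24a (-0.04 ± 0.29; adjusted p = 0.923) and Gfap (0.91 ± 0.55; adjusted p = 0.181; 0.000167 with Scrublet calls removed) did not pass. In total 1463 of 3386 genes passed (848 higher, 615 lower), with 825 without tdTomato-negative library 1 and 230 without library 2. RLE scaling moved the median of all genes by 0.14 on the log2 scale. Every gene named as called had the same direction in both library pairs. Camera passed 9 of 17 lists and 0 with an estimated correlation; cell cycle (1.57e-13) had adjusted p = 0.349 with an estimated correlation, and cilium axoneme (4.88e-21) had adjusted p = 0.330 with an estimated correlation.

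Per cell, cell cycle transcripts made up a median of 0.867 per 1000 UMIs in ependymal-like cells (highest cell 2.83), 1.25 in astrocyte-like cells (highest 8.33) and 19.5 in transit-amplifying-like cells. Above 10 per 1000 UMIs lay 0 of 234 ependymal-like cells, which by counting allows a share of up to 1.28% of that class. So did 0 of 295 astrocyte-like cells and 243 of 270 transit-amplifying-like cells (90.0%). Mki67 and Top2a helped define the classes, so a dividing ependymal cell could lie in another class. These shares describe the classes and set no limit on dividing ependymal cells. Among neuroblast-like cells 82 of 479 (17.1%) lay above that line. In ependymal-like cells the list summed to 872 CPM in the tdTomato-positive library (exact 95% interval 798 to 951), 1579 (1234 to 1992) in tdTomato-negative library 1 and 1450 (1276 to 1640) in library 2. Oligodendrocyte-like cells had sums of 519, 1688 and 1304 in the same libraries, and transit-amplifying-like cells 21606 and 21740 in the tdTomato-negative ones.

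**Figure D5:**
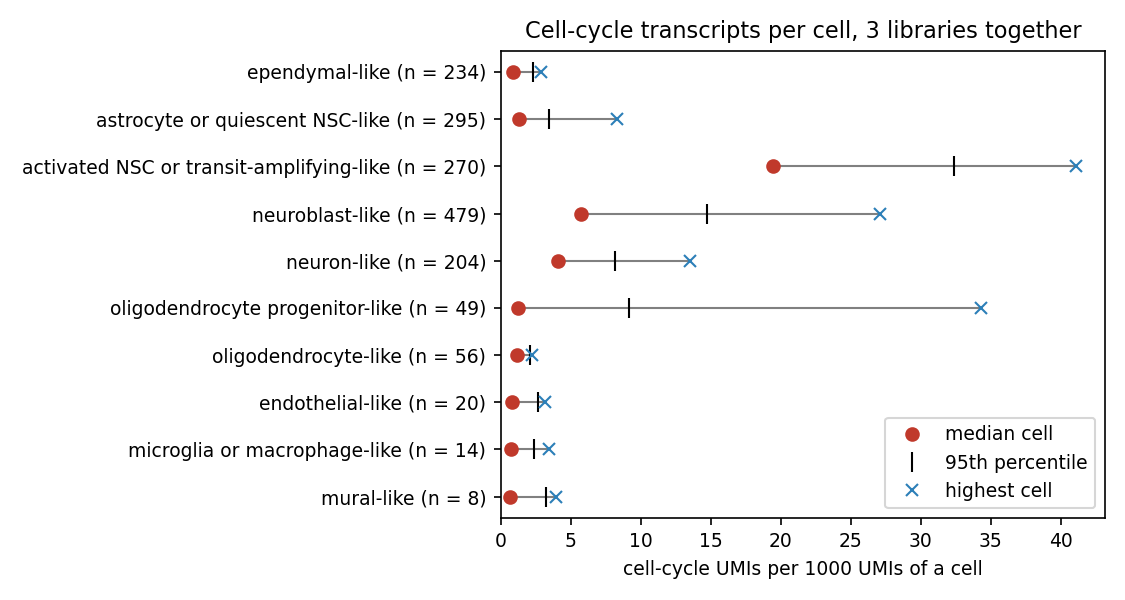
Cell cycle UMIs per 1000 UMIs of a cell in each class, as the median, the 95th percentile and the highest cell. The highest ependymal-like cell lay at 2.83, against a median of 19.5 in transit-amplifying-like cells.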

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

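Of the tests here, those on the genes between the gates, on doublets, on Sox2 and on the splits of the samples were chosen after the results were seen, while the test of free RNA for the endothelial-like and microglia-like cells was chosen before.

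The 62 barcodes removed from the tdTomato-positive library, which were used only when all deposited barcodes were compared between gates, held erythroid markers at 4.99% of their UMIs (3396 UMIs), against 0 UMIs in the barcodes removed from the tdTomato-negative libraries and 0.00278% in the kept cells. Choroid plexus markers made up 0.413% of the UMIs of the same barcodes (281 UMIs), against 0.107% and 0.0259% in the barcodes removed from the tdTomato-negative libraries and 0.0433% in the kept cells. From tdTomato-negative libraries 1 and 2 only 3 and 6 barcodes were removed, with 4 and 2 choroid plexus UMIs, so both contrasts between gates rest on few barcodes. For the myelin gene Mbp and the tubulin-binding gene Stmn1, the tdTomato-positive library lay on opposite sides of both tdTomato-negative ones in ependymal-like and in oligodendrocyte-like cells, and these differences were not tested. In oligodendrocyte-like cells it lay closer to the nearer tdTomato-negative library than these 2 lay to each other, so no change between gates is shown there. Stmn1 was higher by 0.84 on the log2 scale in tdTomato-positive oligodendrocyte-like cells (2782 against 1004 and 2376 CPM) and lower in ependymal-like cells (124 against 623 and 616). Mbp had a log2 difference of -0.14 in oligodendrocyte-like cells (7642 against 8825 and 8026 CPM), while in ependymal-like cells it stood at 348 against 0 and 11.5. The oligodendrocyte-like class differed in makeup between gates: at resolutions 0.5 and 2.0 it held 3 and 20 tdTomato-negative cells in place of 10 and 32, with more in oligodendrocyte precursor-like clusters, and 14 tdTomato-positive cells at both.

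Several genes that passed between gates in ependymal-like cells are abundant in other cells of the library in which they were higher, such as Mbp in oligodendrocyte-like cells, and if free RNA were the source, the other classes of that library, apart from the highest, would hold at least the UMIs that the lower limit of the ependymal excess predicts. For Ucma, Fos and Hist2h2aa1 they held at most 0.249 of the expected UMIs (Ucma 0 against 12.3, exact Poisson p = 4.72e-06; Fos 1 against 10.7, p = 0.00026; Hist2h2aa1 126 against 505, p = 8.44e-91), which argues against free RNA for these 3. For Mbp, Ttr and Gm42418 the UMIs were reached (lowest ratio 0.875, Ttr with 11 against 12.6, exact Poisson p = 0.397), so free RNA may account for them. For Stmn1, Tubb2b, Tubb5, Hist1h2ap and Camk2n1 the test cannot tell, since these classes held at least 1.72 times the UMIs expected at the ependymal-like level, and for Kif5a 3.89 expected UMIs were too few. In astrocyte-like cells, all but Fos and Hist1h2ap lay on the same side of both tdTomato-negative libraries as in ependymal-like cells. Stmn1 was at 62.2 CPM against 464 and 706, Tubb5 at 156 against 345 and 354, and Camk2n1 at 591 against 227 and 225. Mbp was at 404 against 69.1 and 42.8. The tdTomato-positive side rests on 16 cells (Stmn1 on 2 UMIs), and a shift shared by the library was not tested. A biological difference between tdTomato-positive and tdTomato-negative ependymal cells was not tested apart from the gate and stays open for all 12.

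Endothelial-like and microglia-like cells came from the tdTomato-positive library alone, although the GFP gate reads Sox2. Free RNA is argued against, since the cells of each class held at least 93.9% of that class's marker UMIs in the library while taking 4.85% and 3.69% of all UMIs. These markers were open to the clustering and gave the classes their names, so part of this share is built in. Doublets with ependymal cells are argued against by ependymal markers at no more than 8.18% of the level in ependymal-like cells. Transcription of Sox2 at the level of ependymal-like cells is argued against as well, with 1 UMI over 34 cells against 12.8 expected (exact Poisson p = 3.65e-05). How these cells passed the GFP gate stays open, and a biological source tied to the tdTomato gate was not tested.

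The 1046 genes called between ependymal-like and astrocyte-like sums were set against the other splits of the 6 sums into 3 and 3. The real split was 1 of 10 and the highest of the others called 0 genes. The other splits put ependymal-like and astrocyte-like sums in the same group, which can widen the spread and leave few calls. Most of them also part only 1 of the library pairs, unlike the paired design. With these limits, and with 10 splits too few for a share under 0.05, the comparison cannot decide.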

How the results depend on the processing

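The alternatives that split the astrocyte-like class by its Gfap and Thbs4 cluster were chosen after seeing the data. Over 414 pairs of a named gene and a comparison, 4737 values were computed, of which 4428 kept direction and side of the threshold, 282 lost the threshold, 20 gained it and 7 changed direction. In ependymal-like against astrocyte-like cells, the direction changed for Hes1 (0.42 against the Gfap and Thbs4 cluster alone) and Cd200 (-0.15 to 3.05 with 1 library left out). In transit-amplifying-like against astrocyte-like cells it changed for Igfbp2 (2.94 against that cluster alone), Klf2 (0.10 under the stricter cell filter, 1.17 at resolution 2.0) and Cald1 (-0.16 with odd-digit clustering, -0.054 with Scrublet calls removed). Igfbp2 was at 0 CPM in the 2 sums of the Gfap and Thbs4 cluster. Its 2.94 is therefore a fitted value over 0 counts and not a measured size. The cause of these changes in direction was not tested.

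Under DESeq2, 1908 genes passed between gates and 0 between ependymal-like cells of the gates (9 at an unadjusted p under 0.05, against 133 and 12 called in edgeR), and the cause was not tested. Thinned cells left 1518 genes to test and gave 358 between ependymal-like and astrocyte-like, 653 between transit-amplifying-like and astrocyte-like, and 461 between ependymal-like and transit-amplifying-like cells. Leaving out 1 library gave 211 to 955, 237 to 1634 and 230 to 1464, with the fewest genes tested (1306) without tdTomato-negative library 2. Ependymal-like cells against the Gfap and Thbs4 cluster alone gave 604 genes and 7 lists, and the cause was not tested. Without the library block that pairs the classes (no replicate block), 1106, 1385 and 1712 genes passed, each within 1.5 times the count with the block. No paired analysis of the gates was possible because the labels do not match the tdTomato-positive library to a tdTomato-negative one. Leaving out a tdTomato-negative library left 1 against 1 in the gate comparisons, so no test could be made.

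With an estimated correlation, camera passed 0 lists in all 5 comparisons (unadjusted p under 0.05 for 0 between gates, 6 between ependymal-like and astrocyte-like, 0 between transit-amplifying-like and astrocyte-like and 2 between ependymal-like and transit-amplifying-like cells). Fry passed 0 lists between gates, 0 between ependymal-like cells of the gates (4 and 2 at an unadjusted p under 0.05), 13 between ependymal-like and astrocyte-like, 13 between transit-amplifying-like and astrocyte-like and 16 between ependymal-like and transit-amplifying-like cells. In the gate comparisons both checks rest on 1 residual degree of freedom, so 0 lists passing there cannot decide.

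Ependymal-like cells kept their class under every clustering setting (100%), while 53.7% to 84.3% of all cells did. The transit-amplifying-like share of tdTomato-negative library 1 was 11.3% with odd-digit clustering. That of library 2 was 16.4% at resolution 0.5, 17.2% at resolution 2.0, 11.2% with odd-digit clustering and 15.03% with Scrublet calls removed. The astrocyte-like share of library 2 was 18.0% under the stricter cell filter. The neuroblast-like share was 17.8% and 24.98% in libraries 1 and 2 under the stricter filter and 23.05% and 21.9% at resolution 2.0, and in library 2 it was 32.1% with odd-digit clustering and 29.0% with Scrublet calls removed. At resolution 0.5 no cluster was neuroblast-like or neuron-like, and an unnamed cluster held 52.7% and 52.5% of libraries 1 and 2. The neuron-like shares of libraries 1 and 2 were 24.8% and 24.4% with Scrublet calls removed. The oligodendrocyte-like shares were 1.17% and 1.78% at resolutions 0.5 and 2.0, 1.24% and 1.84% under the stricter filter, and 1.56% and 1.78% with odd-digit clustering. In the tdTomato-positive library the astrocyte-like share was 9.92% with odd-digit clustering, 9.52% at resolution 0.5 and 9.05% with Scrublet calls removed, the endothelial-like share was 14.6% under the stricter filter, the transit-amplifying-like share was 0 under the stricter filter and with odd-digit clustering, and the neuroblast-like share 0 under the stricter filter. No cluster was mural-like under the stricter filter, at resolution 0.5, with odd-digit clustering or with Scrublet calls removed. The cause of these moves was not tested. The ependymal-like sum of tdTomato-negative library 1 rests on 12 cells.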

Other observations

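The comparison within the astrocyte-like class, and all tests of it, were chosen after the results were seen. The cluster picked by Gfap and Thbs4 (15 and 78 cells in the tdTomato-negative libraries, 2 sums) was compared with the other astrocyte-like cluster (3 sums), so these 2 genes are no result here. Insulin-like growth factor binding protein 5 (Igfbp5) rose by 3.49 ± 0.38 on the log2 scale (572 ± 78.9 against 31.5 ± 27.7 CPM), Vim by 2.60 ± 0.41, S100a6 by 2.30 ± 0.33, Fos by 3.43 ± 0.51 and Slc38a1 by 4.12 ± 0.72. Among the genes that fell, the glutamate receptor gene Gria2 was at -3.59 ± 0.41, Vegfa at -3.37 ± 0.49 and the phagocytosis receptor gene Mertk at -2.93 ± 0.60. Ribosomal protein genes rose for 52 of 57 (57 adjusted over the list alone), with a camera adjusted p = 2.81e-45 and adjusted p = 0.282 with an estimated correlation. Ion and water transport genes fell for 7 of 17 and rose for 2 (8 and 2 adjusted over the list alone). In all 246 of 3440 genes passed (136 higher, 110 lower). RLE scaling gave 375 (155 higher, 220 lower), DESeq2 177 and no replicate block 162, while 14 passed without tdTomato-negative library 1 and 4 without library 2.

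Marker UMIs of cell types that named no cluster were present in ependymal-like cells. Choroid plexus markers summed to 491, 178 and 265 CPM in the tdTomato-positive library and the tdTomato-negative libraries 1 and 2, fibroblast markers to 22.1, 22.2 and 17.3, and erythroid markers to 25.5, 0 and 0.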
